A study of Mus musculus with 9 samples.

How the data were processed

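RNA from tissue around the infarct was sequenced in 9 mouse libraries, 3 each from sham-operated mice, mice with photothrombosis (PT) given water, and PT mice given Pushen, all at day 28. Per the labels the tissue is brain, while the labels' extraction protocol speaks of retinas; of 18 photoreceptor genes 3 passed the expression filter. Libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The deposited table gives raw read counts per gene and library, and the counter and its settings are not given in the sources used here. The same table gives FPKM, scaled by the authors to gene length and library size. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm8 were used. The coordinates in the deposited table match the later build GRCm38, since 51957 of 55141 gene identifiers shared with GENCODE M21 (94.2%) have the same start and end. The table holds 55401 genes, 21807 of them protein-coding, and all 18 value columns were matched to libraries by name (0 left over). Whether the counts were made by strand is not stated, so genes overlapping others, near-identical gene copies and short RNAs inside longer genes have uncertain values. Xist was near 0 and Ddx3y was present in every library.

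Genes with a mean of at least 0.5 FPKM over all libraries were tested, 16740 in number. Counts were scaled by the trimmed mean of M values, and the 3 groups were fitted together with edgeR 4.0.16 in R 4.3.3. The edgeR quasi-likelihood test was made for each comparison, and p-values were adjusted by the Benjamini-Hochberg method within the comparison. An adjusted p under 0.05 was called changed. Fold changes are log2 values, and their standard error (SE) is the fold change divided by the square root of the quasi-likelihood F. Group means are given with the SD of 3 libraries. Because the labels do not state separate animals, p-values measure only the spread between these libraries.

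Gene lists for cell types and processes, 56 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They list 957 genes, of which 954 are in the table, 839 were tested and 74 are in more than 1 list. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. A list described as called passed this test, and adjusted p-values of lists come from camera unless fry is named. Each list was also tested with a correlation estimated from its own genes and with fry. Counts within a list are given adjusted over all tested genes and again adjusted over the list alone.

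Genes named in the text follow the rule. It takes the 10 largest rises and 10 largest falls of each comparison among genes that passed, with a given symbol, at least 1 FPKM in the higher group and libraries of the groups fully apart. Where fewer than 5 passed, the 5 of smallest p that met the other conditions, groups fully apart included, are named as not passing. Up to 4 genes of smallest p are named per list, and 12 genes in every comparison: Gfap, Aif1, Cd68, Rbfox3, Mbp, Gap43, Bdnf, Vegfa, Nlrp3, Il1b, C3 and Trem2. Genes named outside the rule are said to have been chosen after their values were seen. A gene with no count in a group is given only as at least so many times higher, against a floor of 3 counts per library.

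The shift of Pushen along the PT change was measured with each PT library held out of the choice of genes. Correlations between comparisons that share libraries were set beside 100 simulated draws with all 3 groups unchanged. The pipeline was tested on simulated data with 200 changed genes. Of genes changed 2-fold, 50.7% were found in PT against sham, 44.8% in Pushen against PT and 64.2% in Pushen against sham, with 5, 7 and 4 false calls. Of genes changed 1.5-fold, 7.46%, 14.9% and 11.9% were found. A raised list was called, as was 1 unchanged list. The held-out shift was 0.574% with none simulated and -50.9% with a return of 50% simulated.

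Alternatives tried were other filters, scalings and pseudocounts, DESeq2 1.42.0, fits with only the compared groups, library weights, a block for the replicate number, a 2-fold threshold, and leaving out each library. Chosen after the data were seen were limma-trend on log2 CPM and on FPKM, omission of PT library 1 and Pushen library 2, scaling of the list tests by library size only, and tests of the KEGG terms in the deposited table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some genes that the rule names are not reported here. Dose was not modelled, since each dose has 1 library. Behaviour, infarct size and histology are not given in the sources used here.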

Results

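RNA was sequenced from tissue around a brain infarct in mice at day 28. The infarct was made by photothrombosis (PT), a stroke model in which light closes cortical vessels after a photosensitive dye is given. Sham-operated mice and PT mice received water, and a further group of PT mice received Pushen, a commercial drug preparation given by gavage from 24 h after surgery. Each group held 3 libraries. The labels give the Pushen libraries doses of 391, 392 and 393 mg/kg, which were treated as 1 group. The deposited counts summed to between 66775462 and 72646409 per sham library, 64482908 and 75100133 per PT library, and 57437342 and 73499628 per Pushen library. Between 26579 and 27979 genes had a count, and mitochondrial transcripts took between 7.05% and 9.28% of counts. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

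The largest axis of variation separated sham from infarct libraries. The first principal component, 62.2% of the variance, placed the sham libraries between -89.4 and -73.5, the PT libraries between 35.5 and 64.3, and the Pushen libraries at 45.5, 55.6 and 1.46. Pushen library 3 was thus the infarct library nearest to sham on this axis. The second component, 8.90% of the variance, was negative in sham library 3 (-24.6) and PT libraries 1 and 2 (-47.4 and -16.9). The other libraries lay between 3.69 and 23.5 on it, all Pushen libraries among them. Libraries of a group differed by far more than counting noise, with a chi-square per gene between 46.5 and 166, so none was a copy of another.

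PT was compared with sham to ask which transcripts differed around the infarct at day 28. Genes of activated microglia, reactive astrocytes and antigen presentation were much higher in PT. Gfap, the intermediate filament of astrocytes, rose from 15.1 ± 4.45 to 329 ± 130 FPKM (SD, n = 3 each), a fitted 20.9-fold rise. Its log2 fold change was 4.39 ± 0.42 (SE), and edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.000461. Of 25 disease-associated microglia genes all 25 rose (median log2 fold change 2.81), among them Spp1 (4.87 ± 0.40), Lgals3 (7.14 ± 0.60), Lilrb4a (6.31 ± 0.54) and Gpnmb (7.35 ± 0.65). Of 30 reactive astrocyte genes 29 rose (median 3.19). They included Cxcl10, a chemokine that attracts T cells (5.19 ± 0.35), the complement component C4b (5.11 ± 0.37), the iron-siderophore carrier Lcn2 (6.80 ± 0.53) and the immunoproteasome subunit Psmb8 (2.94 ± 0.24). All 6 measured MHC class II genes rose (median 4.98). Cd74, the invariant chain of class II loading, rose by 5.16 ± 0.25 on the log2 scale, H2-Eb1 by 4.81 ± 0.28, H2-Aa by 5.96 ± 0.42 and H2-Ab1 by 5.45 ± 0.42. Of 15 genes of MHC class I and antigen processing 14 rose (median 2.67), including Nlrc5, the transactivator of class I genes (3.41 ± 0.23), and H2-Q6 (4.03 ± 0.20). The H2-Q genes are near-identical copies, and their values are uncertain where reads can be split between them. Adjusted over the list alone, these 4 lists gave the same counts of 25, 29, 6 and 14. The set test camera, with a preset correlation of 0.01, called each of them higher, and none kept its call with an estimated correlation (adjusted p = 0.169 for each with an estimated correlation).

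Immune cell genes rose with them. All 16 measured monocyte and macrophage genes rose (median 3.82), including the mannose receptor Mrc1 (2.84 ± 0.23), the scavenger receptor Cd36 (5.92 ± 0.54) and Ifitm3 (3.49 ± 0.31). Of 17 complement genes 16 rose, 17 when adjusted over the list alone (median 3.14), with C1qa, C1qb and C1qc, the subunits of C1q, at 3.52 ± 0.29, 3.33 ± 0.29 and 3.27 ± 0.29. Interferon response genes rose in 23 of 24 cases (median 2.79), with Irf9 at 1.91 ± 0.18 and Gbp2, an interferon-induced GTPase, at 3.46 ± 0.33. Of 17 measured cytokine and chemokine genes 16 rose (median 4.14), including Cxcl16 (4.14 ± 0.38) and Ccl5 (4.80 ± 0.51). Of 24 phagocytosis and lysosome genes 21 rose (median 1.77), with the cathepsins Ctsc and Ctss at 2.90 ± 0.28 and 3.64 ± 0.35. Of 6 measured T and NK cell genes 5 rose (median 3.39), including Trac (3.42 ± 0.58) and Nkg7 (6.16 ± 0.87, with 4 counts in all sham libraries). All 8 measured B and plasma cell genes rose (median 4.10), among them the surface receptor Cd22 (5.61 ± 0.66), the antibody light chain Igkc (6.84 ± 0.81) and Jchain (4.25 ± 0.73). Of 19 inflammasome and NF-kappaB genes 16 rose, 17 when adjusted over the list alone (median 1.46), with Tlr2 at 4.18 ± 0.34, the pore-forming Gsdmd at 2.16 ± 0.21 and the adaptor Pycard at 2.44 ± 0.24. For the other 6 of these lists the count adjusted over the list alone was the same. camera called all 8 higher, and none kept its call with an estimated correlation (adjusted p = 0.189 for B and plasma cells, 0.18 for the inflammasome list and 0.169 for the others with an estimated correlation).

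Genes of scar, meninges and vessels were also higher. Of 24 measured fibroblast and fibrotic scar genes 21 rose (median 2.73), including the collagen Col3a1 (5.24 ± 0.48), the collagen cross-linking oxidase Lox (4.06 ± 0.38), Fbln1 (3.32 ± 0.29) and the matrix protease Mmp14 (2.86 ± 0.27). All 12 measured meningeal genes rose (median 1.56), with Aldh1a2, which makes retinoic acid, at 1.90 ± 0.16 and Ptgds at 1.36 ± 0.13. Of 20 endothelial and blood-brain barrier genes 14 rose, 17 when adjusted over the list alone (median 0.47), with the junction protein Cdh5 at 1.00 ± 0.14 and Vwf at 1.28 ± 0.25. Of 14 measured pericyte and smooth muscle genes 10 rose (median 0.79), with Pdgfrb at 1.00 ± 0.16. The other 3 lists kept these counts when adjusted over the list alone. camera called the 4 lists higher; with an estimated correlation the adjusted p = 0.169 for scar and meninges and adjusted p = 0.296 for endothelium and pericytes.

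Homeostatic microglia genes rose in 13 of 17 cases, 14 when adjusted over the list alone (median 0.87), with Tmem119 at 1.32 ± 0.15 and the growth factor receptor Csf1r at 1.80 ± 0.21. Homeostatic astrocyte genes rose in 15 of 17 cases under both adjustments, over all genes and adjusted over the list alone (median 0.46), with the water channel Aqp4 at 1.54 ± 0.22 and the glutamate transporter Slc1a3 at 0.74 ± 0.10. Of 24 oligodendrocyte and myelin genes 14 rose, 18 when adjusted over the list alone (median 0.73), with Cldn11 at 1.29 ± 0.24 and Mobp at 1.02 ± 0.23 (for Mobp, adjusted p = 0.0513 without sham library 1). The mean level of the oligodendrocyte list above sham was 1.03 and 0.97 in PT libraries 1 and 2 but 0.17 in PT library 3, below sham library 3 at 0.24. camera called the 3 lists higher, and their adjusted p = 0.18, 0.257 and 0.448 with an estimated correlation.

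Neuronal genes were lower in PT. Of 18 pan-neuronal genes 13 fell, 15 when adjusted over the list alone (median -0.45), including the synaptic fusion protein Snap25 (-0.75 ± 0.15), the calcium sensor Syt1 (-0.74 ± 0.16), Stmn2 (-0.65 ± 0.14) and Elavl4 (-0.89 ± 0.19). Of 22 synaptic genes 14 fell, 16 when adjusted over the list alone (median -0.41), with Nrxn3 at -0.69 ± 0.15 and Cplx2 at -0.43 ± 0.10. Excitatory neuron genes fell in 4 of 18 cases under both adjustments, over all genes and adjusted over the list alone, among them the glutamate receptor subunits Gria2 (-0.75 ± 0.15) and Grin2a (-0.74 ± 0.15). Of 19 inhibitory neuron genes 8 fell and 1 rose, or 9 and 1 when adjusted over the list alone, with the GABA-making enzyme Gad1 at -0.53 ± 0.10. Cholesterol biosynthesis genes fell in 11 of 22 cases, 14 when adjusted over the list alone (median -0.38), with Hmgcs1 at -0.79 ± 0.13 and Sqle at -0.53 ± 0.10. Immediate early genes, which neurons switch on quickly with activity, moved the other way. Of these 19 genes 11 rose under both adjustments, over all genes and adjusted over the list alone (median 0.74), with Fos at 1.66 ± 0.19, Jun at 1.24 ± 0.15, Egr2 at 2.31 ± 0.31 and Junb at 1.12 ± 0.16. camera called the 5 falling lists lower and the immediate early list higher. None kept its call with an estimated correlation (adjusted p = 0.283 for pan-neuronal, synaptic and cholesterol genes, 0.296 for excitatory and immediate early genes, and 0.257 for inhibitory genes, with an estimated correlation).

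**Figure D1:**
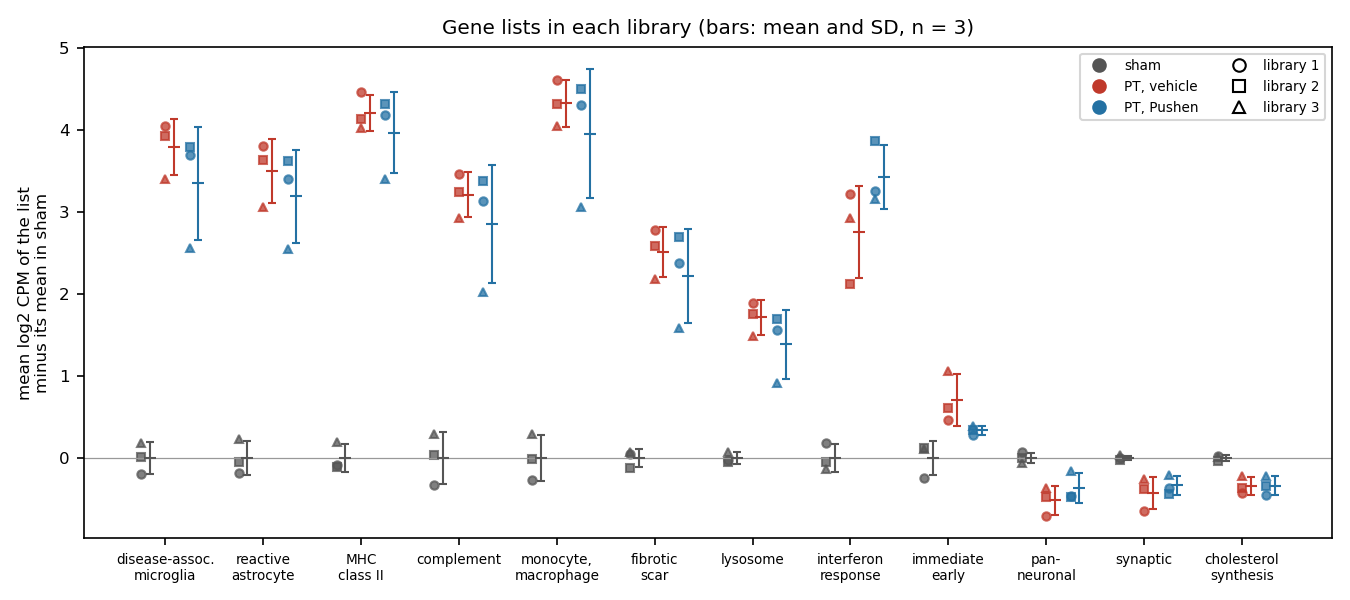
Mean log2 CPM of 12 gene lists in each of the 9 libraries, on the y axis, minus the list's mean in sham. Points are libraries, bars the group mean and SD (n = 3); disease-associated microglia genes lay between 3.41 and 4.05 in PT, and at 3.70, 3.79 and 2.56 in Pushen libraries 1, 2 and 3.

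Among single genes, the 10 with the largest rise in PT had no count in any sham library, so each fold is a lower bound against a floor of 3 counts per library. Ccl8, a monocyte-attracting chemokine, was at least 137-fold higher, the lectin receptor Clec4d at least 82.4-fold, Evi2b, which overlaps another gene, at least 105-fold, the GTPase Gbp10 at least 104-fold and the lipoprotein Apoc2 at least 62.1-fold. The other 5 were antibody light chain segments, Igkv3-4, Igkv3-12, Igkv10-96, Igkv15-103 and Igkv6-23, at least 139-, 117-, 111-, 84.9- and 82.4-fold higher. Most counts of Igkv3-12 and Gbp10 came from PT library 1, and without it their bounds were 14.9- and 42.0-fold; the other bounds stayed within 1.5 times with any PT library left out. In all, 80 tested genes had no sham count, and 69 of them were antibody gene segments, which are near-identical copies and uncertain. Of the 10 largest falls, 4 were short RNAs: Mir3072, Snord50b, Mir128-1 and the transfer RNA mt-Th. Mir3072 had 348 counts over the sham libraries and 3 over the PT libraries; Snord50b had 25 and 3. Such short genes overlap or adjoin longer transcripts, and their counts are uncertain. The remaining 6 were the retinoid isomerase Rpe65 (-2.07 ± 0.53), Btbd6 (-1.97 ± 0.54), Fam126b (-1.89 ± 0.39), Pnma2 (-1.71 ± 0.34), the vesicle fusion adaptor Napb (-1.65 ± 0.51) and the protocadherin Pcdh7 (-1.62 ± 0.23). Napb and mt-Th lost their call without sham library 1, PT library 1, 2 or 3, or Pushen library 1 or 2 (adjusted p = 0.0520, 0.119, 0.0762, 0.0584, 0.0536 and 0.0518 for Napb, and 0.214, 0.134, 0.112, 0.0770, 0.0598 and 0.0630 for mt-Th), and without sham library 1 their fold changes were -0.65 and -0.81. Mir128-1 lost it without the same libraries or sham library 3 (0.157, 0.137, 0.0912, 0.0715, 0.0588, 0.0618 and 0.0953), Btbd6 without sham library 1, 2 or 3 or PT library 1 or 3 (0.0611, 0.0582, 0.0525, 0.0802 and 0.0614) and Rpe65 without sham library 1 (0.0573).

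Among 12 genes named in advance, Aif1 (2.23 ± 0.19), the lysosomal marker Cd68 (3.97 ± 0.38), the microglial receptor Trem2 (3.03 ± 0.30), complement C3 (7.16 ± 1.13), the cytokine Il1b (3.40 ± 0.62) and myelin Mbp (0.93 ± 0.24) rose, as did Gfap. Rbfox3, the neuronal nuclear protein NeuN, fell by 0.45 ± 0.11 on the log2 scale. Mbp lost its call without sham library 1 or 2 or PT library 1 (adjusted p = 0.0698, 0.0674 and 0.0583), and Rbfox3 without sham library 2 or PT library 2 (0.0567 and 0.0551). The growth-associated Gap43 (-0.37 ± 0.18, adjusted p = 0.152), the neurotrophin Bdnf (-0.35 ± 0.30, adjusted p = 0.407) and Vegfa (-0.03 ± 0.13, adjusted p = 0.899) did not pass. Nlrp3, an inflammasome sensor, averaged 0.442 FPKM and lay below the expression filter. Without the filter its log2 fold change was 1.36 ± 0.37 (adjusted p = 0.0362). By the coordinates in the deposited table, which match GRCm38, Gfap lies on chromosome 11 from 102887336 to 102897200 on the minus strand, C3 on chromosome 17 from 57203970 to 57228136 on the minus strand and Cd74 on chromosome 18 from 60803848 to 60812646 on the plus strand.

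Over all 16740 tested genes, edgeR's quasi-likelihood test called 5176 in PT against sham, 3202 higher and 1974 lower. Of these, 1739 changed by at least 2-fold, 1649 higher and 90 lower. camera called 43 of 56 lists, 34 higher and 9 lower; 0 were called with an estimated correlation, and fry, which tests each list alone, called 46. Leaving out sham library 1 gave 3198 genes and sham library 2 gave 3365. The lower genes alone fell to 782, 1000 and 1247 without sham library 1, 2 or 3, and to 1170 and 1299 without PT library 1 or 2. After quantile normalization 2508 were higher and 3480 lower.

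Markers of neighbouring tissue were uneven between the infarct libraries. Of 14 measured striatal neuron genes 5 rose in PT, 9 when adjusted over the list alone, and camera called the list higher (adjusted p = 0.592 with an estimated correlation). The list's mean log2 level above sham was 3.14 in PT library 1, 1.13 in PT library 2 and -0.03 in PT library 3. Its call was lost without PT library 1 (adjusted p = 0.319) and without each of sham libraries 1, 2 and 3 and Pushen libraries 2 and 3 (0.0794, 0.0529, 0.0531, 0.0679 and 0.138). The dopamine receptor Drd2 stood at 20.6 FPKM in PT library 1 and between 0.24 and 2.96 FPKM in the other libraries. Choroid plexus genes rose in 4 of 11 cases, 10 when adjusted over the list alone, and camera called the list higher (adjusted p = 0.454 with an estimated correlation). The mean level of the list was 3.99 in PT library 1 and 3.96 in Pushen library 2, and between 1.25 and 1.95 in the other infarct libraries, against at most 0.42 in sham. Ttr, the main secreted protein of choroid plexus, stood at 528 FPKM in PT library 1, 607 in Pushen library 2 and 146 in Pushen library 3, and between 2.09 and 41.4 elsewhere. Ependymal and cilia genes rose in 8 of 10 cases (median 2.40), with Foxj1 at 2.60 ± 0.38. This list was uneven in sham too, at -0.95, -0.15 and 1.09 in libraries 1, 2 and 3, and sham library 3 stood not far below PT library 3 (1.84). Adjusted over the list alone 9 rose and 1 fell, and the adjusted p = 0.337 with an estimated correlation. Without PT library 1 and Pushen library 2, a choice made after the data were seen, 3465 genes were called in PT against sham, 2 in Pushen against PT and 2049 in Pushen against sham.

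**Figure D2:**
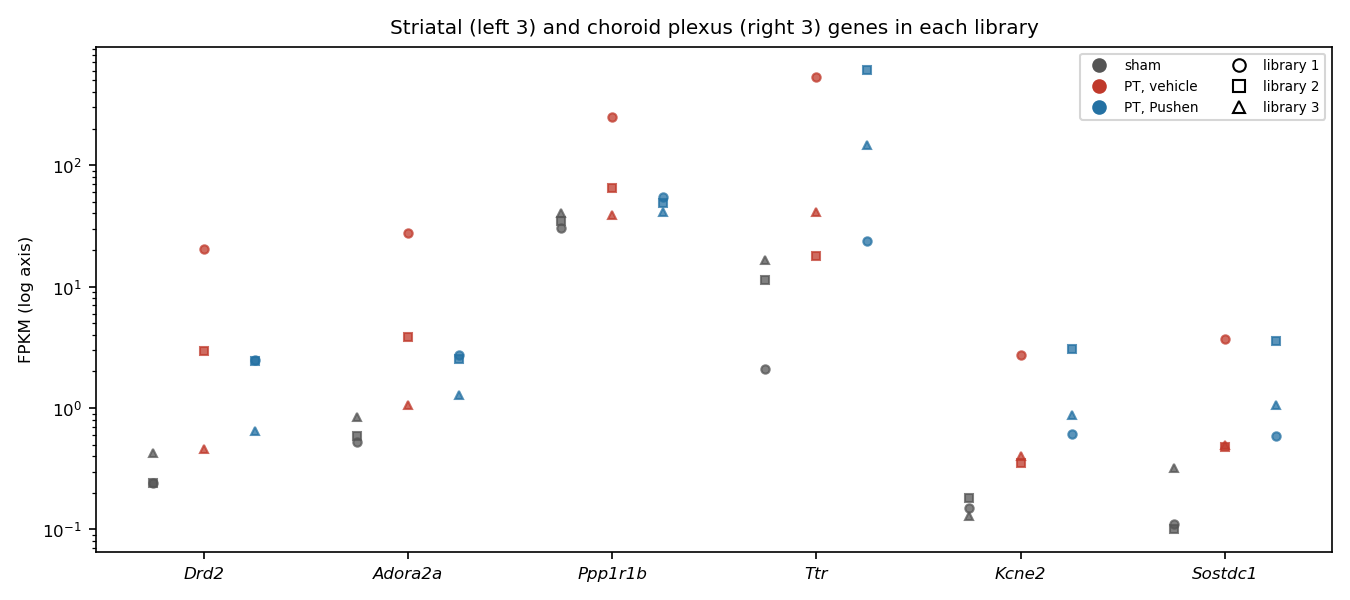
FPKM on a log axis of 3 striatal genes (Drd2, Adora2a, Ppp1r1b) and 3 choroid plexus genes (Ttr, Kcne2, Sostdc1) in each of the 9 libraries. Drd2 stands at 20.6 FPKM in PT library 1; Ttr stands at 528 FPKM in PT library 1 and 607 FPKM in Pushen library 2.

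Pushen was compared with PT to ask which transcripts the treatment changed around the infarct. No single gene passed the test. camera at the preset correlation called 21 of 56 lists, while 0 were called with an estimated correlation and 0 by fry. Interferon response genes were called higher with Pushen, with a median log2 fold change of 0.53 over 24 genes (camera adjusted p = 3.2e-10; adjusted p = 0.693 with an estimated correlation). The antiviral genes Isg15, Ifi44 and Rsad2 stood at 0.97 ± 0.36, 1.18 ± 0.44 and 0.86 ± 0.33, each short of the threshold (adjusted p = 0.707). Immediate early genes were called lower with Pushen, with a median of -0.40 over 19 genes (camera adjusted p = 1.61e-09; adjusted p = 0.693 with an estimated correlation). Junb (-0.72 ± 0.16), Ier2 (-0.71 ± 0.16), the synaptic Arc (-1.37 ± 0.35) and Nr4a1 (-0.90 ± 0.24) had an adjusted p of 0.707 over all genes. Adjusted over the list alone, 7 of the 19 immediate early genes fell and 0 of the 24 interferon genes rose.

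These lists differed in how evenly the libraries showed them. Immediate early genes stood 0.46, 0.61 and 1.07 log2 units above sham in PT libraries 1, 2 and 3, and 0.28, 0.34 and 0.39 in the Pushen libraries. Of 56 lists, this was the 1 with every Pushen library on one side of every PT library, a separation that chance gives in 10% of cases. At that rate chance would separate more than 1 of 56 lists, so the separation is no support for the call. The immediate early median lay between -0.48 and -0.30 with each library left out. Interferon genes stood 3.22, 2.13 and 2.93 above sham in PT and 3.26, 3.87 and 3.16 in Pushen, so that PT library 2 was the lowest and the groups overlapped. Without PT library 2 the list's median was 0.27, without Pushen library 2 it was 0.33, and without PT library 1 it was 0.93; camera called it higher each time.

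Lists of injured tissue were called lower with Pushen by small medians, and no call held with an estimated correlation (adjusted p = 0.693 for each list here with an estimated correlation). Disease-associated microglia genes had a median of -0.31 over 25 genes, with Ch25h at -0.85 ± 0.39 and the cathepsin Ctsd at -0.53 ± 0.28. Phagocytosis and lysosome genes had a median of -0.29 over 24 genes, with Gusb at -0.58 ± 0.24. Reactive astrocyte genes had a median of -0.23 over 30 genes, with Lcn2 at -1.09 ± 0.40 and, in the other direction, Emp1 at 1.73 ± 0.69. Complement (-0.27, 17 genes), fibrotic scar (-0.26, 24 genes) and monocyte and macrophage genes (-0.25, 16 genes) were called lower as well. Homeostatic astrocyte genes had a median of -0.19 over 17 genes, with Aldh1l1 at -0.30 ± 0.08, and endothelial genes a median of -0.17 over 20 genes, with the lipid transporter Mfsd2a at -0.47 ± 0.12. Pan-neuronal genes (0.16, 18 genes, Syt1 at 0.33 ± 0.15) and axon growth genes (0.11, 20 genes, Klf7 at 0.20 ± 0.07) were called higher. Striatal neuron genes were lower, with a median of -1.29 over 14 genes, beside the high level in PT library 1. No member of these 11 lists passed over all genes, and 0 passed adjusted over the list alone.

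Pushen library 3 carried most of these lower calls. Its disease-associated microglia level was 2.56 log2 units above sham, against 3.70 and 3.79 in Pushen libraries 1 and 2 and 4.05, 3.93 and 3.41 in the PT libraries. Without Pushen library 3 the median of that list was -0.06 (adjusted p = 0.816) and that of reactive astrocytes was -0.02 (adjusted p = 0.895). The lysosome, complement, scar, macrophage, pan-neuronal and axon growth calls were lost too (adjusted p = 0.224, 0.686, 0.895, 0.806, 0.79 and 0.219). Medians without that library were -0.08 for lysosome, 0.01 for complement, -0.05 for scar and 0.11 for macrophage genes, so complement and macrophage medians changed sign. Without PT library 1 reactive astrocyte, complement, scar, macrophage, pan-neuronal, axon growth and striatal genes lost their call (adjusted p = 0.302, 0.188, 0.226, 0.526, 0.226, 0.263 and 0.958). Without PT library 2 reactive astrocyte and macrophage genes lost theirs (adjusted p = 0.0524 and 0.0531). The immediate early, interferon, homeostatic astrocyte and endothelial lists were called with each of the 9 libraries left out.

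For single genes the smallest adjusted p was 0.375, for Sepsecs, an enzyme of selenocysteine synthesis, at 0.80 ± 0.11 (1.55 ± 0.202 FPKM in PT, 2.72 ± 0.0346 in Pushen and 2.69 ± 0.121 in sham; SD, n = 3). The other 4 genes that met the rule with the smallest p among rises were the mitochondrial transport GTPase Rhot1 (0.69 ± 0.14), the squalene synthase Fdft1 (0.60 ± 0.12), Ripor2 (0.39 ± 0.08) and Mpv17l (1.29 ± 0.27). Among falls they were Sox8 (-0.53 ± 0.09), Rbm38 (-0.90 ± 0.16), the arrestin Arrb2 (-0.50 ± 0.09), Coa7 (-1.18 ± 0.23) and the channel Trpm3 (-1.54 ± 0.32). All 9 had an adjusted p of 0.707. The rule takes only genes with Pushen and PT libraries fully apart, so this holds for all 10 by choice and is no result. Over all tested genes 2045, or 12.2%, had the groups fully apart, against 10% by chance. Of the genes named in advance none passed. Gfap stood at -0.43 ± 0.37, C3 at -0.64 ± 0.85, Cd68 at -0.29 ± 0.34, Trem2 at -0.40 ± 0.28, Aif1 at -0.08 ± 0.18, Il1b at -0.82 ± 0.54, Mbp at -0.29 ± 0.24 and Rbfox3 at -0.02 ± 0.11. Gap43 stood at 0.13 ± 0.18, Bdnf at 0.10 ± 0.30, Vegfa at 0.04 ± 0.13 and, without the filter, Nlrp3 at -0.26 ± 0.36.

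**Figure D3:**
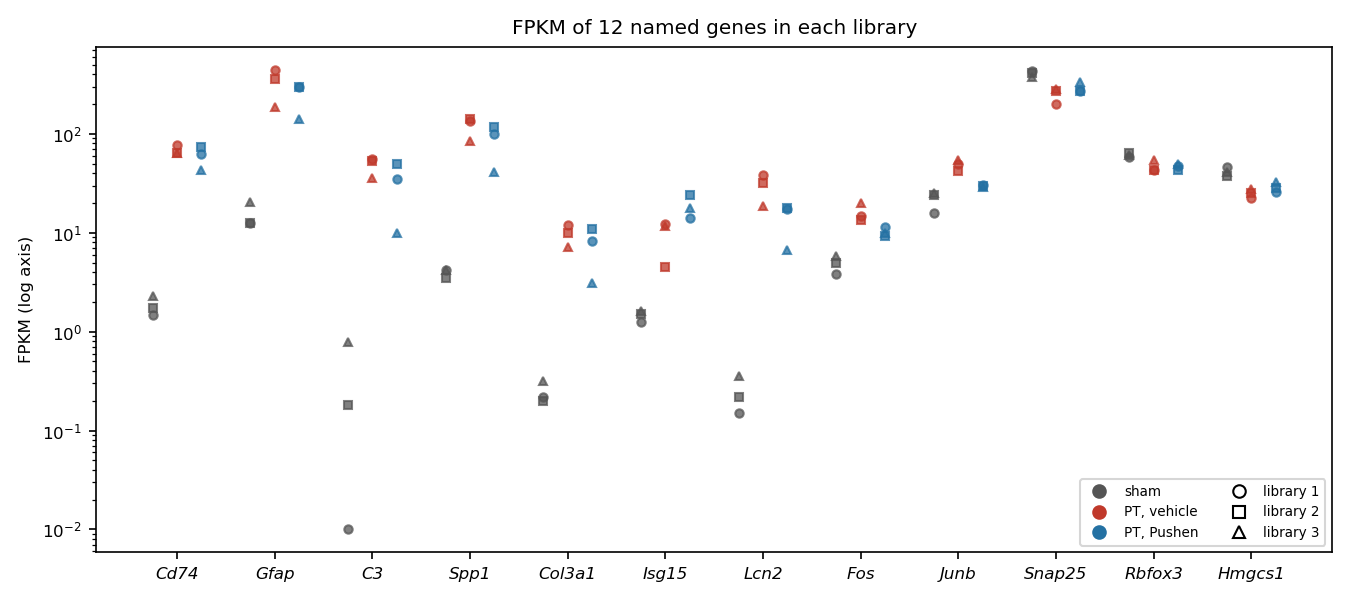
FPKM on a log axis of 12 named genes in each of the 9 libraries, with groups by colour and libraries by symbol. Gfap lies between 12.5 and 20.3 FPKM in sham, between 187 and 443 in PT and between 141 and 301 in Pushen; Junb lies between 42.2 and 54.8 in PT and between 29.0 and 30.8 in Pushen.

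edgeR's quasi-likelihood test called 0 of 16740 genes in Pushen against PT, with 1086 at an unadjusted p under 0.05 where 837 were expected by chance. limma-trend on log2 CPM also called 0, DESeq2 called 49 (20 higher, 29 lower) and limma with library weights called 4. Of the DESeq2 genes, 8 were at 0 FPKM in all 3 Pushen libraries. They were Pet117 and 7 genes of liver products, Alb, Gc, Fabp1, Serpina3k, Serpina1e, Serpina1c and Mup20, all chosen after their values were seen. Pet117 stood at 6.88, 9.24 and 10.7 FPKM in PT libraries 1, 2 and 3. In sham it stood at 10.2 in library 1 and at 0 in libraries 2 and 3, so its values were uneven within sham too. It was also the gene called with only the compared groups. Alb stood at 18.4 and 13.2 FPKM in PT libraries 1 and 2, at 11.98 in sham library 3, at 0.02 in sham library 2 and at 0 in the other 5 libraries. Other DESeq2 genes had FPKM above 0 in every library. Among them Rhot1, Fdft1 and Mpv17l were higher and Arc was lower in Pushen (DESeq2 adjusted p = 0.0039, 0.00783, 0.0023 and 0.0156). The 4 genes with library weights, named after their values were seen, were Rhot1, Sepsecs, Coa7 and Gm10273. The median confidence interval of a fold change reached 0.346 log2 units to each side, and 83.0% of genes had an interval within 2-fold. In simulated counts for this comparison the test found 44.8% of genes changed 2-fold and 14.9% of those changed 1.5-fold, so a small change in most genes was not detectable here. Of the 21 lists that camera called, 3 were higher and 18 lower. Leaving out PT library 1 gave 11 lists and Pushen library 3 gave 8. Leaving out sham library 1, PT library 3 or Pushen library 2 gave 1 gene each (Pet117, Sike1 and Tef), and leaving out Pushen library 3 gave 5 (among them Gatad2b, Coa7, Gm10273 and Mir3072), all named after their values were seen.

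Pushen was also compared with sham, to give the state of treated infarct tissue against the same reference. Most of the gene groups that differed in PT differed here in the same direction. All 25 disease-associated microglia genes rose (median 2.52), with Lgals3 at 7.05 ± 0.60 and Spp1 at 4.38 ± 0.39. Of 30 reactive astrocyte genes 28 rose, 29 when adjusted over the list alone (median 3.04), with Cxcl10 at 5.26 ± 0.35, C4b at 4.88 ± 0.37 and the filament Vim at 3.20 ± 0.27. All 6 MHC class II genes rose (median 4.70), with Cd74 at 4.96 ± 0.24 and H2-Aa at 5.86 ± 0.41. Interferon response genes rose in 22 of 24 cases, 23 when adjusted over the list alone (median 3.65), with Ifitm3 at 3.80 ± 0.31 and Gbp2 at 3.69 ± 0.34. Of 24 fibrotic scar genes 20 rose (median 2.43), with Col3a1 at 4.84 ± 0.47 and the proteoglycan Dcn at 3.72 ± 0.36. The microglia, MHC class II and scar counts were the same when adjusted over the list alone. camera called the 5 lists higher, and with an estimated correlation the adjusted p = 0.119 for microglia and scar, 0.116 for astrocytes and interferon, and 0.103 for MHC class II.

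Fewer neuronal genes passed against sham here than in PT, a difference between counts that is not a test of Pushen against PT. Of 18 pan-neuronal genes 2 fell, Rbfox3 (-0.47 ± 0.11) and Snap25 (-0.55 ± 0.15), and 11 fell when adjusted over the list alone. Rbfox3 lost its call without sham library 2 or 3 or Pushen library 1 or 2 (adjusted p = 0.0775, 0.0588, 0.0694 and 0.0829), and Snap25 without sham library 1, 2 or 3, PT library 2 or Pushen library 1 or 2 (0.126, 0.106, 0.0677, 0.0594, 0.144 and 0.139). Of 22 synaptic genes 4 fell under both adjustments, over all genes and adjusted over the list alone, including the complexins Cplx1 (-0.48 ± 0.11) and Cplx2 (-0.48 ± 0.10); Cplx1 lost its call without sham library 2 or 3 or Pushen library 1 or 2 (0.0697, 0.0627, 0.0746 and 0.0746). Cholesterol biosynthesis genes fell in 6 of 22 cases, 11 when adjusted over the list alone, with Hmgcs1 at -0.60 ± 0.13 and Msmo1 at -0.67 ± 0.14; Hmgcs1 lost its call without sham library 1 or Pushen library 1 or 2 (0.0567, 0.0626 and 0.0591). camera called the 3 lists lower, and the adjusted p = 0.358, 0.352 and 0.267 with an estimated correlation. Of 19 immediate early genes 4 rose under both adjustments, over all genes and adjusted over the list alone, among them Jun (0.84 ± 0.15), Egr2 (1.65 ± 0.31) and Fos (0.99 ± 0.19), and camera did not call the list (adjusted p = 0.108).

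The 10 largest rises against sham again had no sham count. They were Ccl8, at least 160-fold higher, Gbp10, at least 148-fold, and 8 antibody segments. The segments Igkv3-4, Igkv15-103, Igkv10-96, Igkv1-135, Ighv1-80, Igkv6-23 and Ighv8-8 were at least 163-, 132-, 127-, 76.5-, 75.1-, 69.4- and 62.6-fold higher, and Igkv3-5 completed the set; all 8 are near-identical copies. Without Pushen library 2 the bounds of Igkv3-4, Igkv10-96, Ighv8-8 and Gbp10 were 81.3-, 54.8-, 40.2- and 59.0-fold, and the others given stayed within 1.5 times with any Pushen library left out. Igkv3-5, at 10.3 ± 15.9 FPKM in Pushen, had 914 counts in Pushen library 2 and 35 and 25 in libraries 1 and 3. It lost its call without sham library 1, 2 or 3 or PT library 2 (adjusted p = 0.0865, 0.0869, 0.0767 and 0.0522). The largest falls were the T cell receptor segment Trbj2-2, with 16 counts over the sham libraries and 3 over the Pushen libraries, Rpe65 (-2.13 ± 0.53), the transcription factor Foxp1 (-1.40 ± 0.34), Rprd1b (-1.36 ± 0.34), Xkr4 (-1.33 ± 0.24), Stxbp5l (-1.31 ± 0.35), Col19a1 (-1.19 ± 0.34), Hsbp1l1 (-1.18 ± 0.28), the potassium channel Kcna3 (-1.14 ± 0.27) and Zfp865 (-1.11 ± 0.28). Of these falls Xkr4 kept its call with each library left out. The other 9 each lost it without 3 or more libraries, at an adjusted p of up to 0.135 for Trbj2-2, 0.151 for Col19a1, 0.102 for Rprd1b, 0.101 for Stxbp5l, 0.0920 for Rpe65, 0.0875 for Zfp865, 0.0870 for Foxp1, 0.0821 for Kcna3 and 0.0806 for Hsbp1l1. Of the genes named in advance, Gfap (3.95 ± 0.41), Aif1 (2.15 ± 0.19), Cd68 (3.68 ± 0.38), Trem2 (2.63 ± 0.30), C3 (6.53 ± 1.10) and Il1b (2.57 ± 0.61) rose and Rbfox3 fell; Il1b lost its call without Pushen library 1 or 2 (adjusted p = 0.0736 and 0.0563). Mbp (0.64 ± 0.24, adjusted p = 0.0981), Gap43 (-0.24 ± 0.18, 0.389), Bdnf (-0.24 ± 0.30, 0.611), Vegfa (0.02 ± 0.13, 0.948) and, without the filter, Nlrp3 (1.10 ± 0.37, 0.118) did not pass.

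In total 2718 genes differed between Pushen and sham, 2261 higher and 457 lower, and 1334 by at least 2-fold, 1313 higher and 21 lower. camera called 44 of 56 lists, 33 higher and 11 lower; 0 were called with an estimated correlation and fry called 42. Leaving out sham library 1 or 2 gave 1660 or 1538 genes, leaving out Pushen library 1 or 2 gave 1568 or 1594, and library weights gave 6134 (3511 higher, 2623 lower). The lower genes alone fell to 113, 107 and 149 without sham library 1, 2 or 3 and to 84 and 100 without Pushen library 1 or 2. They rose to 869 without Pushen library 3 and to 1168 and 755 without PT library 1 or 3. The higher genes were 1431 without sham library 2 and 1484 and 1494 without Pushen library 1 or 2. The count of lower genes is thus uncertain. After quantile normalization 1695 were higher and 1126 lower.

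The infarct groups shared most of their calls against sham. Of the 2261 genes higher in Pushen 2175 (96.2%) were higher in PT, where independent lists would share 432, and of the 457 lower genes 387 (84.7%) were lower in PT, where independent lists would share 53.9. The overlap was not computed with a library left out, where the lower genes in Pushen ranged from 84 (without Pushen library 1) to 1168 (without PT library 1). With all groups simulated as unchanged and the simulated sham libraries shared by both comparisons, 20 draws called a mean of 0 genes in PT and 0.1 in Pushen, too few to give an overlap. Over all tested genes 85.0% had the same sign in both, against 66.6% in the simulation. Fold changes over genes, which are not independent replicates, correlated with r = 0.924, against 0.5001 simulated. Their covariance was 0.848, against 0.0558 simulated, a difference of 0.792. The simulated libraries held no infarct change, so the values of r are not comparable. The simulated values give only what shared sham libraries add by themselves. The 3 sham libraries cannot be divided evenly between the comparisons, and part of the excess overlap may come from these shared controls. Among genes higher in PT, the Pushen change was a median of 83.6% of the PT change, and among genes lower in PT 63.6%; these genes were chosen on the PT libraries, which favours larger PT changes.

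**Figure D4:**
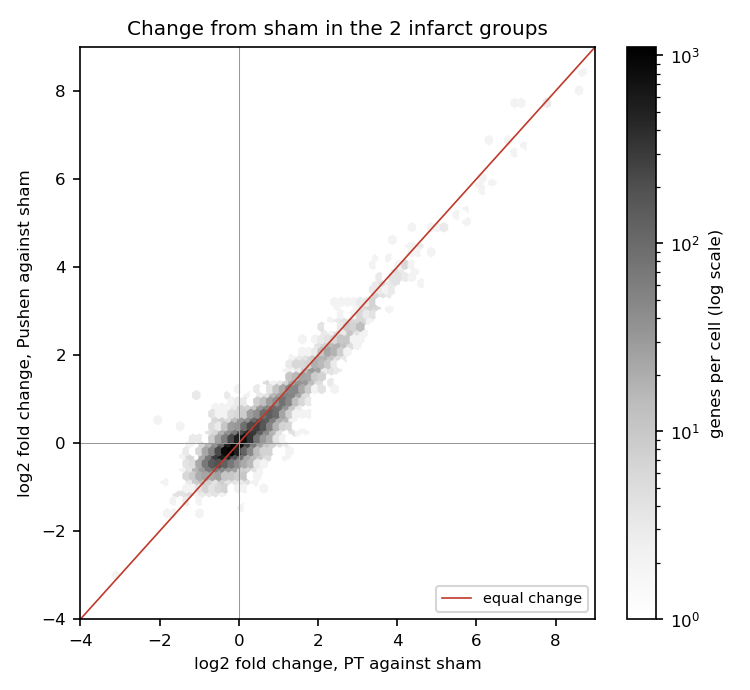
Log2 fold change of each tested gene in Pushen against sham (y axis) and in PT against sham (x axis), as counts of genes per cell on a log grey scale; the line marks equal change. Genes follow the line with r = 0.924, and 68 of the 16740 genes lie outside the axes.

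Whether Pushen moved the PT change toward sham was tested with each PT library held out of the choice of genes. The shift along the PT change was -0.37, -0.16 and 0.03 log2 units with PT libraries 1, 2 and 3 held out. The mean was -0.17 ± 0.199 (SD, n = 3 held-out PT libraries) against a PT change of 1.19, or -14.1%, where a negative value is toward sham. The 3 values share the same Pushen and sham libraries, so this SD leaves out the spread between Pushen libraries. The values had both signs, and an exact permutation test of 3 libraries against 3 can give no two-sided p below 0.1. PT libraries 1 and 2, which gave the negative shifts, were also negative on the second principal component, where no Pushen library was. Genes of the PT change stood 1.502, 1.231 and 0.850 above sham in the PT libraries and 1.12, 1.18 and 0.77 in the Pushen libraries. Each PT value is over the genes chosen without that library (3806, 4128 and 5829 genes). Each Pushen value is a mean over these 3 choices, so PT and Pushen values here are not on the same genes. Without Pushen library 3 the shift was -0.03, and without Pushen library 2 it was -0.27. Fold changes of PT against sham and of Pushen against PT, which share the PT libraries, correlated over genes with r = -0.418, against -0.498 ± 0.0218 (SD of 100 draws) simulated with unchanged groups. The simulated libraries had no PT change either, and a PT change widens the fold changes, so these values of r are not comparable. Genes were drawn independently, so the SD leaves out correlation between genes. The covariance of these fold changes was -0.162, against -0.0555 simulated, a difference of -0.106. Without Pushen library 3 the covariance was -0.0487 and r was -0.118; without PT library 3 they were -0.268 and -0.529. With each other library left out the covariance lay between -0.235 and -0.118.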

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

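The omission of PT library 1 and Pushen library 2, limma-trend and scaling by library size only were chosen after the data were seen. Named genes were followed in 14 settings: other filters, DESeq2 size factors, quantile normalization, the replicate block and each library left out. They were not followed with DESeq2 itself, library weights, only the compared groups, limma-trend, FPKM, or without PT library 1 and Pushen library 2. In the 14 settings no called gene among those named turned direction. Of 9712 results there, over 703 pairs of gene and comparison, 514 lost a call, 75 gained one and 9123 stayed on the same side of the threshold, called or not. In 54 of these, called in neither setting, the sign changed. Genes changed in PT against sham fell from 5176 to 1739 at 2-fold and ranged from 3198 to 5799 with a library left out. In Pushen against sham they went from 2718 to 1334 at 2-fold and 6134 with library weights, and ranged from 1538 to 3736 with a library left out. A 2-fold threshold can only remove calls; for the weights the cause was not tested. In Pushen against PT 0 became 1 with only the compared groups, 49 with DESeq2, 4 with library weights, 2 without PT library 1 and Pushen library 2, and 0 to 5 with a library left out; the cause was not tested. With an estimated correlation the lists called went from 43, 21 and 44 to 0, 0 and 0 in PT against sham, Pushen against PT and Pushen against sham, since most estimates lie above 0.01. fry, which does not compare a list with other genes, called 0 lists in Pushen against PT. With a library left out, 8 to 31 lists were called there. The correlation of PT against sham with Pushen against PT ranged from -0.529 to -0.118 with a library left out. The shift ranged from -0.27 to -0.03 with a sham or Pushen library left out. These moves were below its SD over held-out PT libraries, which leaves out the spread between Pushen libraries. Other filters, scalings, FPKM in place of counts and limma-trend left every total within 1.5 times, but not the lower genes alone. These went from 1974 to 3480 in PT against sham with quantile normalization, 3427 with library weights, 1011 without PT library 1 and Pushen library 2, and 90 at 2-fold. In Pushen against sham they went from 457 to 1126 with quantile normalization, 225 and 219 with FPKM, 1104 with DESeq2, 1239 with only the compared groups, 2623 with library weights, 239 with library size only and 21 at 2-fold; the cause was not tested. A pseudocount of 0.1 was not run for tests on counts, which use none. At this depth and n, a 1.5-fold change was found in 14.9% of simulated genes in Pushen against PT.

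The replicate numbers gave no clear sign of pairing, though 3 libraries per group cannot exclude it. Deviations of same-numbered libraries correlated between -0.225 and 0.0846. The own number was best in 0 of 3 for sham and PT, 2 for PT and Pushen and 0 for sham and Pushen. With the replicate block 4266, 0 and 2108 genes and 42, 22 and 43 lists were called in PT against sham, Pushen against PT and Pushen against sham, and 242 genes were lower in Pushen than in sham; the cause was not tested.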

Other observations

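The tests of KEGG terms, the second lists of striatal and choroid plexus genes, and the tests of single libraries were chosen only after the results were seen. Further lists differed between PT and sham. Cholesterol efflux and lipid genes rose in 16 of 17 cases (median 1.36), with the lipid carriers Apod at 2.81 ± 0.26 and Apoe at 2.66 ± 0.34, and antioxidant genes rose in 13 and fell in 1 of 20, with their regulator Nfe2l2 at 1.86 ± 0.22 and Hmox1 at 3.20 ± 0.40. Iron and ferroptosis genes rose in 9 and fell in 1 of 14: the ferritin Ftl1 rose (2.38 ± 0.30) and the transferrin receptor Tfrc fell (-0.97 ± 0.16). Apoptosis genes rose in 9 and fell in 1 of 19, or 11 and 1 when adjusted over the list alone, with the death receptor Fas at 2.02 ± 0.32. Angiogenesis genes rose in 8 of 15 cases, 9 when adjusted over the list alone, with Angpt2 at 1.87 ± 0.28. Glucocorticoid response genes rose in 10 and fell in 1 of 14, with Mt2 at 1.57 ± 0.22. Neural progenitor genes rose in 10 of 14, with Igfbpl1 at 4.25 ± 0.65, and ribosomal protein genes in 25 of 35, 28 when adjusted over the list alone, with Rplp0 at 0.87 ± 0.12. Oligodendrocyte progenitor genes rose in 8 and fell in 1 of 14, or 9 and 1 when adjusted over the list alone, cell cycle genes rose in 5 of 7, with Mcm2 at 0.82 ± 0.13, and neutrophil genes in 2 of 5. Where a single count is given it was the same when adjusted over the list alone. camera called these 11 lists higher, and none with an estimated correlation (adjusted p = 0.181, 0.222, 0.18, 0.181, 0.283, 0.283, 0.296, 0.349, 0.349, 0.335 and 0.283 in this order with an estimated correlation). The cell cycle call was lost without PT library 1, PT library 3 or Pushen library 3 (adjusted p = 0.057, 0.0544 and 0.0514). Of 14 listed neutrophil genes 5 were measured, 4 with positive fold changes and 1 with a negative one. The largest was in Lcn2 (6.80), also a reactive astrocyte gene, so the neutrophil list does not measure neutrophils alone. Ngp stood at 1.44, 0.59 and 1.59 FPKM in sham libraries 1, 2 and 3 and at 0.76, 1.76 and 0.85 in PT. S100a9 stood at 3.04, 1.77 and 4.07 FPKM in sham and at 5.36, 6.43 and 5.87 in PT.

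Lists called lower in PT were neuropeptides, where 4 of 17 fell, with Sst at -0.47 ± 0.13, cortical layer genes, where 2 of 17 fell (0 adjusted over the list alone), with Rorb at -0.46 ± 0.14, and nuclear oxidative phosphorylation, where 5 of 28 fell (0 adjusted over the list alone), with Ndufs1 at -0.39 ± 0.10. Sst and Rorb lost their call without any 1 of sham libraries 1, 2 and 3 and PT libraries 1 and 2 (adjusted p = 0.0908, 0.0508, 0.0641, 0.0597 and 0.0824 for Sst, and 0.0917, 0.0627, 0.0898, 0.0976 and 0.102 for Rorb), and Ndufs1 without sham library 1 or 2 (0.0631 and 0.0527). In a list of GABA, glutamate and potassium transport 4 fell and 2 rose of 14, with the potassium channel Kcnq3 at -0.65 ± 0.12. With an estimated correlation the adjusted p = 0.349, 0.185, 0.454 and 0.342. The last call was lost without sham library 3, PT library 2 or Pushen library 3 (adjusted p = 0.0516, 0.0683 and 0.0621). Lists not called held genes that changed: the regeneration factor Atf3 rose (4.53 ± 0.57) while the transcription factor Klf7 fell (-0.46 ± 0.07), Tgfb1 rose (2.47 ± 0.27), the hexokinase Hk2 rose (1.90 ± 0.21) and the heat shock gene Hspb1 rose (2.08 ± 0.28). The axon growth list had a median of -0.31 and a mean of 0.13, so they differ in sign. Median, mean or direction of the test differed in sign in 2, 7 and 1 of the 56 lists in PT against sham, Pushen against PT and Pushen against sham, none of them called. The 13 mitochondrially encoded genes were not called in PT (camera adjusted p = 0.0684). In the KEGG terms of the deposited table camera called 70 of 299 higher and 34 lower in PT, with 42 rising and 5 falling of 62 genes of ECM-receptor interaction and 10 falling of 44 genes of aminoacyl-tRNA biosynthesis, and 0 terms with an estimated correlation. In Pushen against PT it called 2 higher and 13 lower, and 0 with an estimated correlation.

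In Pushen against PT, lists lower by small medians beside those described were pericyte (-0.27), inflammasome (-0.25), cholesterol efflux (-0.25), homeostatic microglia (-0.24), neutrophil (-0.32), meningeal (-0.18), NRF2 (-0.11) and ribosomal protein genes (-0.10), none with a member that passed, and none with an estimated correlation (adjusted p = 0.693 for each with an estimated correlation). Without Pushen library 3 the first 7 lost their call (camera adjusted p = 0.404, 0.725, 0.806, 0.147, 0.806, 0.812 and 0.686). Medians were then -0.15 for pericyte, -0.12 for inflammasome, -0.05 for efflux, -0.13 for homeostatic microglia, -0.01 for neutrophil and -0.06 for meningeal genes. Without PT library 1 pericyte, inflammasome, microglia, neutrophil, meningeal, NRF2 and ribosomal genes lost it (0.201, 0.226, 0.0984, 0.0625, 0.174, 0.329 and 0.307), and without PT library 2 efflux, neutrophil, meningeal and NRF2 genes (0.0531, 0.218, 0.325 and 0.232). NRF2 genes lost it also without sham library 1, 2 or 3 (0.0611, 0.0544 and 0.0622). All 5 measured neutrophil genes had negative fold changes, the largest in Lcn2 (-1.09), also a reactive astrocyte gene, so that list does not measure neutrophils alone. Adjusted over the list alone, 1 gene passed in each of 3 further lists, Fdft1 higher and Trpm3 and the antibody chain Ighm (-1.31 ± 0.35) lower. Beside the liver genes named earlier, Cyp2e1 and Mup3 had the same distribution. In all, 9 genes chosen after their values were seen stood at 0.5 FPKM or more in sham library 3 and PT libraries 1 and 2, and at 0.05 FPKM or less in the other 6. Of 84 choices of 3 libraries, no other choice held more than 1 such gene. The same 3 libraries were the only ones with negative values on the second principal component. They include PT libraries 1 and 2 but no Pushen library. Whatever sets them apart is thus partly confounded with Pushen against PT.

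In Pushen against sham, 3 lists were called that were not called in PT. Thalamic genes rose in 5 of 12 cases, 6 when adjusted over the list alone. Circadian clock genes fell in 3 and rose in 1 of 16, or 5 and 1 when adjusted over the list alone. None of the 13 mitochondrially encoded genes passed, and 0 passed adjusted over the list alone, while camera called the list lower. With an estimated correlation the adjusted p = 0.352, 0.373 and 0.541. The thalamic call was lost without sham library 1, 2 or 3, PT library 1 or 3 or Pushen library 2 (camera adjusted p = 0.0535, 0.0554, 0.0562, 0.0575, 0.0600 and 0.0928). The clock call was lost without sham library 2, PT library 1, 2 or 3 or Pushen library 1 or 3 (0.0813, 0.0558, 0.0517, 0.0501, 0.0872 and 0.0713), and the mitochondrial call without sham library 1 or Pushen library 1 or 3 (0.142, 0.0554 and 0.0792).

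The lower injury lists in Pushen were weighed first, 14 lists grouped after the data were seen. Without Pushen library 3 their mean median went from -0.249 to -0.0661 and 2 of 14 kept the call. This is the observation that led to the question of less injured tissue in that library, and not a separate test of it. In 0 of 14 lists did every Pushen library lie below every PT library. With 3 libraries per group and a shift this small, that leaves open a lower level in every Pushen library. Homeostatic astrocyte genes kept -0.18 of -0.19 without Pushen library 3. Thinning all libraries to 57437342 counts moved the medians by 0.00757 on average. Thinning takes counts from all genes in proportion before rescaling, so little movement was likely whatever the cause, and depth is not excluded by it. Whether library 3 differs by dissection, infarct size or response to Pushen was not tested.

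Striatal genes were highest in PT library 1, and choroid plexus genes in PT library 1 and Pushen library 2. In a second list of 9 striatal genes the median was 1.61 higher in PT library 1 than in the other infarct libraries, as striatal tissue in the dissected piece predicts. In 4 infarct libraries it was not above the sham range, while the first list was above it in all but PT library 3. Both lists thus argue against a PT effect in every infarct library, and an effect in some stays open. For choroid plexus a second list of 10 genes stood 0.920 higher in the lower of PT library 1 and Pushen library 2, between the bounds set for and against tissue in the piece, which leaves it open. Its median was 0.59 to 1.85 in the 6 infarct libraries and at most 0.07 in sham, so its rise was not confined to these 2 libraries, and a rise with the infarct itself stays open.

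Immediate early genes were lower in Pushen. The difference between day and night clock genes was -0.17 ± 0.135 (SE), which does not settle whether the time of day at collection differed. Without PT library 3, the highest, the median was -0.30 and the list was still called at camera's preset correlation (adjusted p = 0.00192), so the call does not rest on that library alone. With all libraries the list was not called with an estimated correlation (adjusted p = 0.693) or by fry (adjusted p = 0.610). No test here separates an effect of Pushen on these genes from a difference in handling.

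Among the 10 splits of 6 libraries into groups of 3 no share under 0.05 is possible. In PT against sham 5176 genes and 43 lists stood beside at most 1 gene and 39 lists in another split, and 1 split, the real grouping, reached the real value for each. In Pushen against sham 2718 genes and 44 lists stood beside at most 2 genes and 42 lists, and again 1 split reached them. In Pushen against PT 0 genes stood beside 9 in another split, so that all 10 splits had as many, and 21 lists stood beside 39, with 6 splits calling as many. Mixed groupings called many lists in every comparison. Every other split mixes the compared groups unevenly, so it keeps part of any real difference, and its lists are no measure of chance. Mixing also widens the spread within groups where the real groups differ, so few called genes were likely there. Correlated genes within lists or a structure among the libraries would each give many lists too, and these were not separated.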
